A study of Mus musculus with 6 samples.

How the data were processed

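Total RNA from 6 cultures of mouse CD4+ T cells was labelled with biotin and hybridised to 1-colour Affymetrix Mouse Gene ST arrays, 1 array per culture, starting from 1 ug of RNA per the labels' protocols. Groups and replicate numbers were taken from the sample titles, which give 4 anti-CD3 and 2 anti-CD3 plus anti-ICOS arrays and state no batch. The values deposited by the authors are normalized intensities per probe set on a linear scale, between 7.23 and 22176. MAS5 is the only tool named, per the submitters' processing notes. The normalization method, background correction, probe summary and annotation version are not given in the sources used here, so any centring of the deposited intensities stays unknown. If the arrays were set to equal overall levels, a shift of most genes in 1 direction would not be seen.

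Of 34760 probe sets, 21640 carried 1 gene symbol in the platform annotation, 1321 carried several and 11799 were unnamed here. Probe sets with 1 symbol were used, and a gene with several (954 genes) was represented by its brightest probe set, which gave 19937 genes. One of the 14 genes fixed by name had no such probe set and is not reported here. Since the table was linear, values were analysed as log2(intensity + 16), as laid down for that case, and the offset makes the fold change of dim genes smaller. No filter on expression was used.

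The 2 groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual degrees of freedom) on all 6 arrays. Adjusted p-values are two-sided and Benjamini-Hochberg adjusted over all genes, with 0.05 as the threshold, and differences are anti-CD3 plus anti-ICOS minus anti-CD3. Lists of genes were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 33 lists, and again with an estimated correlation and with fry. The 22 pathway lists and 11 lists of cell type markers were written before the data were examined, and 507 of their 563 entries were measured. An exact permutation test of 1 gene, with its 1-sided p multiplied by 2, cannot go below 0.133 with these group sizes. The genes named are the 10 with the largest rise and the 10 with the largest fall among genes past the threshold with both anti-ICOS arrays outside the anti-CD3 range. Where fewer than 10 passed, those of smallest p were taken and named as not past the test. The genes fixed by name and, from each list, the 3 members of smallest p were added.

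The steps were tested on simulated data for this comparison, with 200 of 19937 genes changed in 5 runs. The fit recovered 85.2% of 2-fold and 97.0% of 4-fold changes with 9.8 false calls per run. Camera called 5 of 5 shifted lists and 1 of 100 unshifted lists. Each value was drawn independently, without correlation between genes and without a shift shared by the genes of 1 array. These rates therefore do not cover lists of genes that move together. Nor do they cover calls of single genes where 1 array lies far from its group in many genes, as anti-CD3 replicate 4 did. The alternatives tried were quantile normalization, median centring, a filter on the dimmest 40% of genes, a trended and robust prior, array quality weights, the mean of a gene's probe sets, every probe set, offsets of 1 and 64, replicate number as a block, each array left out in turn, a minimum change of 1.5-fold and a threshold of 0.1. A fit with anti-CD3 replicate 4 as the only reference, in which replicates 1 to 3 add only to the spread, was added after the data were seen. Array coordinates were not used here. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.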

Results

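Gene expression was measured in mouse CD4+ T cells after a second stimulation through the T cell receptor, with or without the costimulatory receptor ICOS. Naive cells from B6 spleen had first been activated through CD3 and CD28 for 2 days and rested. They were then coated for 20 min with antibody to CD3 alone or to CD3 and ICOS together, and the bound antibodies were cross-linked for 8 h. Each of the 6 cultures was read on 1 Affymetrix Mouse Gene ST array, 4 with anti-CD3 and 2 with anti-CD3 plus anti-ICOS. The labels call the arrays of a group biological replicates, and p-values measure the spread between these arrays. Median probe set intensities lay between 109 and 114 on the 6 arrays. The number of arrays, above all the 2 with anti-ICOS, limits the precision.

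Anti-CD3 replicate 4 differed from the other anti-CD3 arrays in genes of many kinds. Pdk1, a kinase that inhibits pyruvate dehydrogenase, read 10.08 on the log2 scale in replicate 4 against 10.64, 10.64 and 10.60 in replicates 1 to 3, and 9.74 and 9.86 with anti-ICOS. Lyz2, the lysozyme gene of myeloid cells, read 8.53 in replicate 4 against 6.71, 6.70 and 6.77 in replicates 1 to 3, and 8.47 and 9.67 with anti-ICOS. An array is called apart from its group where its gap to the nearest other array, over the range of the 4 anti-CD3 arrays, exceeded Dixon's limit. Across probe sets, which are not independent replicates, replicate 4 correlated with the anti-ICOS arrays at Pearson r = 0.994 and 0.995, and with anti-CD3 replicates 1 to 3 at 0.971, 0.977 and 0.965. The first principal component held 75.3% of the variance and placed replicate 4 at 20.4, beside the anti-ICOS arrays at 23.4 and 20.7 and away from replicates 1 to 3 at -19.9, -17.4 and -27.2. The labels give no batch, so every comparison was also made without replicate 4 and with replicate 4 as the only reference.

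**Figure D1:**
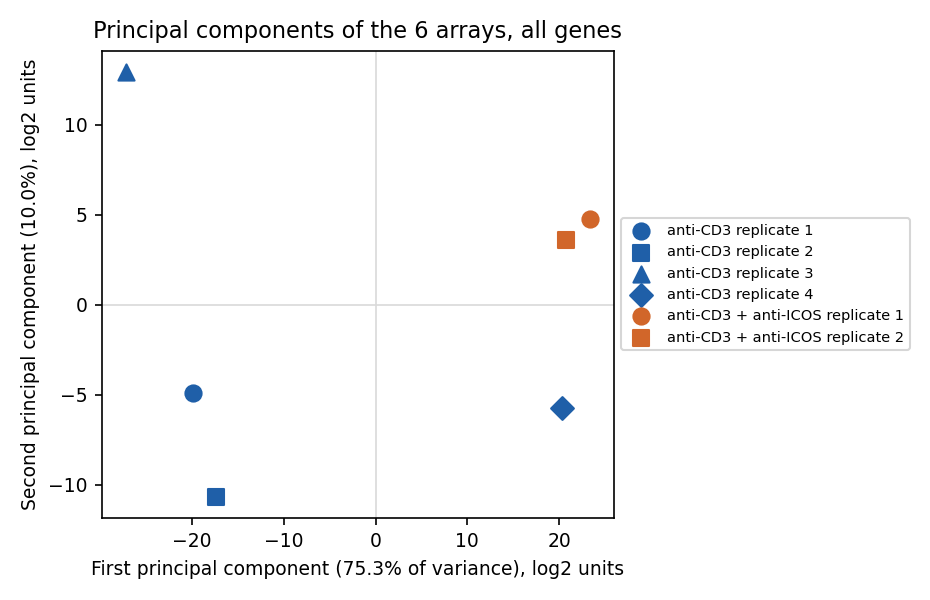
First and second principal components (log2 units) of all 19937 genes on the 6 arrays, 1 point per array, blue for anti-CD3 and orange for anti-CD3 plus anti-ICOS. Anti-CD3 replicate 4 lies at 20.4 on the first component, with the anti-ICOS arrays at 23.4 and 20.7, and the other anti-CD3 arrays lie between -27.2 and -17.4.

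The comparison asks which transcripts differ when ICOS is engaged together with CD3. With anti-ICOS, 54 of 19937 genes changed, and all 54 were higher. Apol7c, of the apolipoprotein L family, rose most, from 6.26 ± 0.014 (SD, n = 4) to 10.01 ± 0.50 (SD, n = 2) on the log2 scale, a difference of 3.75 ± 0.18 (SE, limma adjusted p = 0.00210). Fscn1, which encodes the actin-bundling protein fascin, rose by 2.49 ± 0.20 (adjusted p = 0.00547), from 8.35 ± 0.32 (SD, n = 4) to 10.84 ± 0.15 (SD, n = 2). Csf2rb2 and Csf2rb, beta subunits of the receptors for IL-3 and GM-CSF, rose by 2.42 ± 0.15 (adjusted p = 0.00232) and 2.09 ± 0.21 (adjusted p = 0.0157), and as close paralogs they can share probe signal.

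The carbonic anhydrase gene Car1 rose by 2.09 ± 0.11, the receptor kinase gene Grk3 by 1.91 ± 0.16 and the membrane-bound metalloproteinase gene Mmp25 by 1.89 ± 0.20 (adjusted p = 0.00232, 0.00675 and 0.0207). Ifitm3, an interferon-induced membrane protein gene, rose by 1.84 ± 0.12 and the annexin gene Anxa3 by 1.76 ± 0.11, each with adjusted p = 0.00232. Within the anti-CD3 group, replicate 2 lay apart for Ifitm3 at 6.24 and replicate 1 for Anxa3 at 5.96. Tbc1d8 rose by 1.80 ± 0.14 (adjusted p = 0.00444). These 10 genes were chosen with both anti-ICOS arrays above all 4 anti-CD3 arrays, which favours a pass against replicate 4 alone. Without anti-CD3 replicate 4 all 10 of these genes were past the threshold, and with it as the only reference 10 of 10 as well. Without anti-CD3 replicates 1, 2 or 3 it was 8, 7 or 7 of them, and without anti-ICOS replicates 1 or 2 it was 8 or 6. The call of Csf2rb ended without any 1 array other than anti-CD3 replicate 4 (adjusted p up to 0.150), and that of Mmp25 without anti-CD3 replicates 1, 2 or 3 or anti-ICOS replicate 2 (up to 0.129). That of Grk3 ended without anti-CD3 replicates 2 or 3 or either anti-ICOS array (up to 0.0765), and that of Fscn1 without anti-ICOS replicate 2 (0.0641). Tested over every probe set, Csf2rb and Mmp25 were not past the threshold (adjusted p = 0.0964 and 0.109), nor was Mmp25 with an offset of 64 (adjusted p = 0.0624). Of the 54 genes 31 rose at least 2-fold. Both anti-ICOS arrays lay above all 4 anti-CD3 arrays in each of the 54, a separation that the choice by a small p favours. Over all 19937 genes both lay above in 1696 and both below in 2940, where chance gives 6.67% of genes in each direction. Beside these genes, the fixed dendritic cell marker list lay higher with anti-ICOS by a median of 0.11, and the NK cell list by 0.51.

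**Figure D2:**
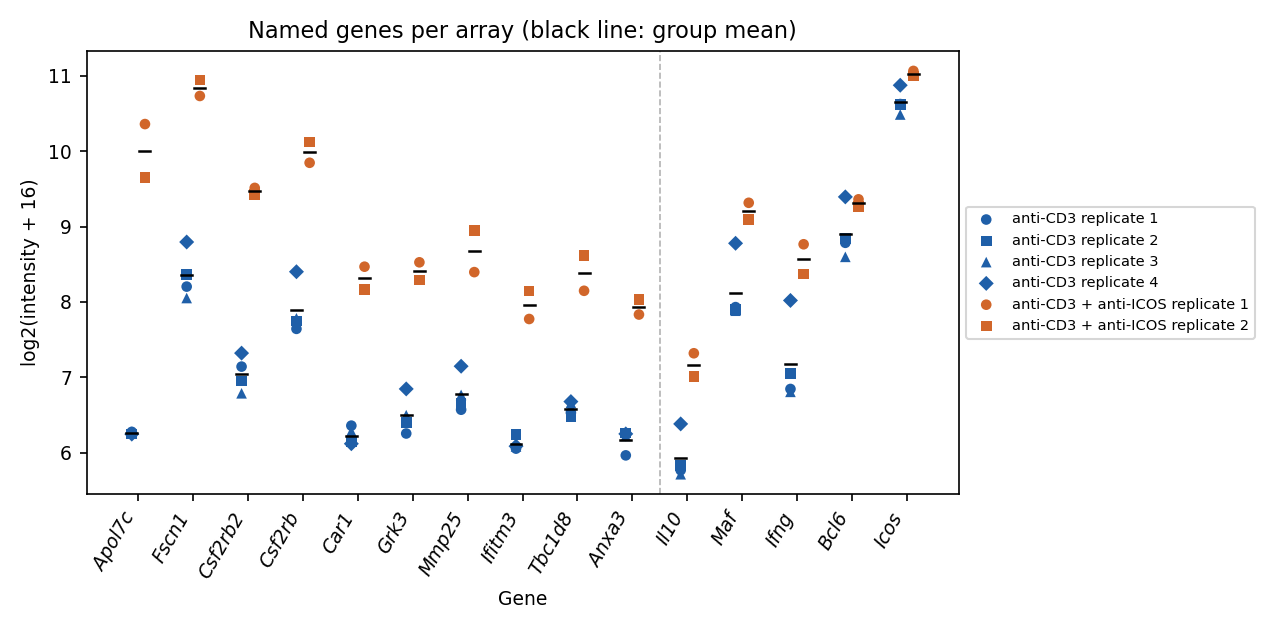
Expression as log2(intensity + 16) of the 10 genes with the largest rise (left of the dashed line) and of Il10, Maf, Ifng, Bcl6 and Icos (right), 1 point per array, with the group mean as a black line. Both anti-ICOS arrays lie above all 4 anti-CD3 arrays for the 10 genes on the left, while for Bcl6 anti-CD3 replicate 4 lies above both anti-ICOS arrays.

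No gene passed the test in the lower direction. By limma with Benjamini-Hochberg adjustment 0 genes were lower, although at an unadjusted p under 0.05 there were 1245 higher and 1109 lower genes. The count of lower genes was 2526 without anti-CD3 replicate 4, 4870 with array quality weights and 0 with replicate 4 as the only reference. Fam183b had the smallest p among lower genes, with a difference of -0.53 ± 0.096 (adjusted p = 0.141). The next, in order of p, were Hexim2 at -0.42, Cpm at -0.39, Spdye4a at -0.38, Wdr19 at -0.46 and Igsf23 at -0.34. The chemokine receptor gene Cx3cr1 at -0.49, Ptgir at -0.39, Klhl6 at -0.37 and Atp7b at -0.50 followed, with adjusted p up to 0.271. For Klhl6 and Atp7b, anti-CD3 replicate 4 lay apart from the rest of its group, toward the anti-ICOS values.

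The count depended on single arrays. Without anti-CD3 replicate 4 it was 5930 genes, 3404 higher and 2526 lower, and these included all 54; without anti-CD3 replicates 1, 2 or 3 it was 18, 16 or 20, all among the 54. Without anti-ICOS replicate 1 it was 36 genes, 23 of them among the 54, and without anti-ICOS replicate 2 it was 26, with 15 among the 54. With replicate 4 as the only reference, and replicates 1 to 3 adding only to the estimate of spread, 35 genes were higher and 0 lower, with 30 of the 54 among them. Of the 123 genes named by the fixed rules 15 passed with all 6 arrays weighted alike and 111 without replicate 4. With array weights 116 passed, and with replicate 4 as the only reference 13. Most of the 123 were chosen by a small p in these same data, which favours a pass. In the same order, 54, 5930, 9413 and 35 of all 19937 genes passed.

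None of the 13 measured genes fixed for the ICOS pathway and T helper function passed the test with all 6 arrays weighted alike. The array weights were uneven within the anti-CD3 group, at 4.53 for replicate 1 against 1.07, 0.38 and 0.15 for replicates 2 to 4. With array weights 11 of the 13 passed, all but Il21 and Il4, 8 higher and 3 lower, and the same 11 did without anti-CD3 replicate 4, while with replicate 4 as the only reference 0 passed. The cytokine gene Il10 differed by 1.24 ± 0.20 (adjusted p = 0.0958), Ifng by 1.39 ± 0.34 (adjusted p = 0.327) and Maf, a transcription factor gene that acts downstream of ICOS, by 1.08 ± 0.26 (adjusted p = 0.310), with anti-CD3 replicate 4 apart from its group for Maf. Bcl6 and Cxcr5, which mark follicular helper cells, differed by 0.41 ± 0.20 and 0.46 ± 0.22 (adjusted p = 0.423 and 0.423), and Foxp3 by 0.80 ± 0.30 (adjusted p = 0.417). Icos itself differed by 0.38 ± 0.11, Il2 by 0.56 ± 0.20, Il4 by 0.40 ± 0.20, Il21 by 0.063 ± 0.066, Cd28 by -0.28 ± 0.093, Cd3e by -0.27 ± 0.11 and Klf2 by -0.22 ± 0.071. For Il21 anti-CD3 replicate 2 lay apart. Without replicate 4, Il10 was higher by 1.39 (adjusted p = 0.000125), Maf by 1.30 (adjusted p = 7.87e-05) and Bcl6 by 0.57 (adjusted p = 0.00295). Against replicate 4 alone the differences were 0.78, 0.43 and -0.079, and none of these 3 passed the test.

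Lists of T helper genes lay higher with anti-ICOS. So did marker lists of some other cell types, with medians of 0.51 for NK cells and 0.39 for mast cells and basophils. B cell markers were not called. Of 18 measured follicular helper genes 0 passed the test over all genes and 2 passed adjusted over the list alone, with a median difference of 0.18 (camera adjusted p = 0.000943, adjusted p = 0.266 with an estimated correlation). Pdcd1 in this list differed by 0.54 ± 0.098, with anti-CD3 replicate 4 apart, and Slamf6 by -0.17 ± 0.064. Among Th17 genes, Tmem176b rose by 1.54 ± 0.20 (adjusted p = 0.0472), 6 of 13 were higher and 1 lower adjusted over the list alone, and the list median was 0.23 (camera adjusted p = 0.000157, adjusted p = 0.195 with an estimated correlation). Il23r differed by 0.80 ± 0.11 and Ahr by 0.80 ± 0.13. Among Th2 genes, Nfil3 rose by 0.82 ± 0.11 (adjusted p = 0.0450), 3 of 16 were higher adjusted over the list alone, and the median was 0.17 (camera adjusted p = 0.000595, adjusted p = 0.266 with an estimated correlation). Of 16 Th1 genes 0 passed over all genes and 3 adjusted over the list alone, with a median of 0.26 (camera adjusted p = 0.000446, adjusted p = 0.270 with an estimated correlation); Hlx differed by 0.34 ± 0.089 and Ccl3 by 1.37 ± 0.38. Of 18 regulatory T cell genes 0 passed over all genes and 4 adjusted over the list alone, with a median of 0.32 (camera adjusted p = 1.15e-05, adjusted p = 0.289 with an estimated correlation). Nt5e differed by 0.41 ± 0.090 and Tnfrsf9 by 0.54 ± 0.15, with anti-CD3 replicate 4 apart for Tnfrsf9. The calls of Tmem176b and Nfil3 ended with replicate 4 as the only reference (adjusted p = 0.174 and 0.114). That of Tmem176b also ended without anti-CD3 replicates 1, 2 or 3 or anti-ICOS replicate 2 (up to 0.220), and that of Nfil3 without any 1 array other than anti-CD3 replicate 4 (up to 0.215). Over every probe set the adjusted p was 0.199 for Tmem176b and 0.160 for Nfil3, with an offset of 64 it was 0.124 and 0.0917, and with quantile normalization it was 0.0642 for Nfil3. The Th2 list was not called with the filter on dim genes (median 0.11, camera adjusted p = 0.0509), and its median was 0.093 without anti-ICOS replicate 1. Quantile normalization gave medians of 0.099 for the follicular and 0.14 for the Th17 list, and the filter gave 0.75 for the Th17 list. Against replicate 4 alone the follicular list was not called (median 0.027, camera adjusted p = 0.130), and the medians were 0.15 for Th17, 0.051 for Th1 and 0.049 for regulatory T cell genes. In anti-CD3 replicate 4 the follicular and regulatory lists lay 0.28 and 0.29 above replicates 1 to 3, against 0.27 and 0.43 with anti-ICOS.

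Genes induced by T cell receptor, NF-kB and interferon signalling also lay higher. Of 22 NF-kB targets Relb alone rose over all genes, by 0.67 ± 0.087 (adjusted p = 0.0455), and 10 were higher adjusted over the list alone, with a list median of 0.33 (camera adjusted p = 1.03e-11, adjusted p = 0.275 with an estimated correlation). Cd83 differed by 0.68 ± 0.12 and Nfkbie by 0.45 ± 0.099. Of 23 genes of the type I interferon response 0 passed over all genes and 13 adjusted over the list alone, with a median of 0.46 (camera adjusted p = 3.19e-12, adjusted p = 0.270 with an estimated correlation). Rtp4 differed by 1.62 ± 0.29, Oasl2 by 1.31 ± 0.24 and Stat2 by 0.49 ± 0.10. The 2 anti-ICOS arrays were unlike here. Less the mean of anti-CD3 replicates 1 to 3, the interferon list mean was 0.89 and 0.41 on them and 0.24 in replicate 4. Of 27 early T cell receptor response genes 0 passed over all genes and 4 adjusted over the list alone, with a median of 0.20 (camera adjusted p = 1.32e-09, adjusted p = 0.266 with an estimated correlation). Jun differed by 0.85 ± 0.14, Dusp5 by 0.52 ± 0.092 and Ier3 by 0.58 ± 0.11. Of 30 effector cytokine genes 0 passed over all genes and 6 adjusted over the list alone, with a median of 0.27 (camera adjusted p = 5.81e-06, adjusted p = 0.241 with an estimated correlation), and the mean of this list set anti-CD3 replicate 4 apart from its group. Csf1 differed by 0.38 ± 0.076 and Ccl1 by 0.28 ± 0.066. Of 28 ICOS, CD28 and PI3K pathway genes 0 passed over all genes and 5 adjusted over the list alone, with a median of 0.14 (camera adjusted p = 9.11e-06, adjusted p = 0.331 with an estimated correlation). Cd80 differed by 0.53 ± 0.10, Icosl by 0.55 ± 0.11 with anti-CD3 replicate 4 apart, and Pik3cb by 0.55 ± 0.12. Cd83 and Cd80 are also on a list of mature dendritic cell genes written after the calls were seen, in which both anti-ICOS arrays lay above all 4 anti-CD3 arrays in 10 of 12 measured genes, against 6.67% by chance. With replicate 4 as the only reference Relb was not past the threshold (adjusted p = 0.118, and up to 0.426 without any 1 array other than anti-CD3 replicate 4), and the ICOS, CD28 and PI3K list was not called (median 0.0073, camera adjusted p = 0.159). The call of Relb also ended with a trended and robust prior (adjusted p = 0.0604), over every probe set (adjusted p = 0.160) and with an offset of 64 (adjusted p = 0.0624). Against replicate 4 alone the medians were 0.13 for NF-kB targets, 0.25 for the interferon response, 0.10 for early T cell receptor response genes and 0.080 for effector cytokines. Without anti-CD3 replicate 3 the ICOS, CD28 and PI3K median was 0.093. Relative to anti-CD3 replicates 1 to 3, the median of NF-kB targets was 0.22 in replicate 4 and 0.39 with anti-ICOS, that of the interferon response 0.20 in replicate 4 and 0.54 with anti-ICOS, and that of the ICOS, CD28 and PI3K list 0.27 in replicate 4 and 0.19 with anti-ICOS.

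Proliferation and glycolysis genes lay lower with anti-ICOS, and about as low in anti-CD3 replicate 4. Of 35 cell cycle genes 0 passed over all genes, 25 were lower and 1 higher adjusted over the list alone, and the list median was -0.66 (camera adjusted p = 3.93e-10, adjusted p = 0.325 with an estimated correlation). The replication gene Mcm4 differed by -0.53 ± 0.13, E2f1 by -0.56 ± 0.17 and Cdk6 by 0.40 ± 0.12. Of 19 glycolysis genes 0 passed over all genes and 0 adjusted over the list alone, with a median of -0.69 (camera adjusted p = 2.83e-06, adjusted p = 0.325 with an estimated correlation). Pgk1 differed by -0.87 ± 0.24, Slc2a3 by -0.44 ± 0.13 and Pdk1 by -0.69 ± 0.17. Relative to anti-CD3 replicates 1 to 3, the cell cycle list lay at -0.79 in replicate 4 and -0.83 with anti-ICOS, and the glycolysis list at -0.81 and -0.87. Against replicate 4 alone the medians were -0.070 and -0.10, and the glycolysis list was not called (camera adjusted p = 0.110). Both the glycolysis list mean and Pdk1 set replicate 4 apart from its group.

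Among the other pathway lists, the chemokine receptor gene Ccr9 rose by 1.37 ± 0.095 (adjusted p = 0.00321), and 7 of 22 adhesion and migration receptors were higher and 1 lower adjusted over the list alone, with a median of 0.26 (camera adjusted p = 5.81e-06, adjusted p = 0.314 with an estimated correlation). Ccr2 differed by 1.05 ± 0.26 and Ccr4 by 0.81 ± 0.20. Ribosome biogenesis genes had a median of 0.28 (camera adjusted p = 2.97e-06, adjusted p = 0.325 with an estimated correlation), with 0 of 22 passing either way. Rrp12 differed by 0.33 ± 0.10, Nop56 by 0.32 ± 0.10 and Bop1 by 0.58 ± 0.19. The amino acid transport and ATF4 list had a median of 0.064 (camera adjusted p = 0.00180, adjusted p = 0.315 with an estimated correlation), with 7 of 24 higher and 1 lower adjusted over the list alone. Slc3a2 differed by 0.42 ± 0.078, Atf3 by 0.54 ± 0.11 and Slc7a11 by 1.10 ± 0.25. Heat shock and folding genes had a median of 0.13 (camera adjusted p = 0.000996, adjusted p = 0.314 with an estimated correlation), with 2 of 17 higher adjusted over the list alone. Xbp1 differed by 0.41 ± 0.088, Hspa5 by 0.39 ± 0.098 and Hsph1 by 0.70 ± 0.22. Inhibitory receptors had a median of 0.11 (camera adjusted p = 0.0297, adjusted p = 0.356 with an estimated correlation), with 4 of 13 higher and 2 lower adjusted over the list alone. Klrg1 differed by 0.95 ± 0.16 and Cd101 by -0.29 ± 0.079, with anti-CD3 replicate 3 apart for Cd101. Apoptosis and survival genes had a median of 0.091 (camera adjusted p = 0.0184, adjusted p = 0.356 with an estimated correlation), with 0 of 19 passing either way. Pmaip1 differed by 0.44 ± 0.13, Mcl1 by 0.35 ± 0.12 and Bcl2l1 by 0.30 ± 0.087, with anti-CD3 replicate 4 apart for Bcl2l1. With replicate 4 as the only reference the ribosome biogenesis, inhibitory receptor and apoptosis lists were not called (camera adjusted p = 0.306, 0.674 and 0.598), and without replicate 4 the amino acid list was not (camera adjusted p = 0.120). Against replicate 4 alone the adhesion median was 0.025, that of ribosome biogenesis 0.018, that of inhibitory receptors -0.027 and that of apoptosis genes 0.027. Without anti-CD3 replicate 3 the inhibitory receptor list was not called (median 0.061, camera adjusted p = 0.0957). The filter on dim genes ended the calls of inhibitory receptors, apoptosis, amino acid and heat shock genes (camera adjusted p = 0.505, 0.236, 0.176 and 0.0503), and array weights ended the first 3 (camera adjusted p = 0.0950, 0.0737 and 0.177). Quantile normalization gave medians of 0.061, 0.0062 and 0.025 for these 3 lists. Without anti-CD3 replicate 4 the inhibitory receptor median was 0.20 and the apoptosis median 0.19. Without anti-ICOS replicate 2 the apoptosis median was 0.052 and the amino acid median 0.14, and without anti-ICOS replicate 1 the heat shock median was 0.083. The ribosome biogenesis median relative to replicates 1 to 3 was 0.36 in replicate 4 and 0.37 with anti-ICOS.

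The remaining 4 pathway lists were not called by camera, and 0 of their members passed over all genes or adjusted over the list alone. The median of FOXO1 and KLF2 targets was -0.0096 (camera adjusted p = 0.592), with Il7r at -0.18 ± 0.095 and Btg1 at 0.28 ± 0.12, the latter with anti-CD3 replicate 4 apart. The T cell receptor complex and its proximal signalling genes had a median of -0.0081 (camera adjusted p = 0.548), with Cd4 at -0.33 ± 0.12, Sla at -0.29 ± 0.10 and Malt1 at 0.36 ± 0.13. Cholesterol biosynthesis genes had a median of -0.040 (camera adjusted p = 0.465), with Nsdhl at -0.28 ± 0.090, Idi1 at 0.34 ± 0.13 and Dhcr7 at -0.29 ± 0.12. Oxidative phosphorylation genes had a median of -0.013 (camera adjusted p = 0.430), with Ndufv1 at -0.23 ± 0.091, Atp5b at -0.23 ± 0.097 and Ndufa9 at -0.26 ± 0.12. With replicate 4 as the only reference the FOXO1 and KLF2 targets were called lower (median -0.087, camera adjusted p = 0.00514), as was the T cell receptor complex list (median -0.071, camera adjusted p = 0.0221), and cholesterol biosynthesis was called higher (median 0.030, camera adjusted p = 0.0261). In the order given these calls had adjusted p = 0.466, 0.699 and 0.466 with an estimated correlation.

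Among the fixed markers of other cell types 1 gene passed the test over all genes. Flt3, the receptor of a dendritic cell growth factor, rose by 1.26 ± 0.087 (adjusted p = 0.00321), and 4 of 10 dendritic cell markers were higher adjusted over the list alone, with a median of 0.11 (camera adjusted p = 0.000431, adjusted p = 0.195 with an estimated correlation). Siglech differed by 0.53 ± 0.080 and Zbtb46 by 0.34 ± 0.078. Of 8 NK cell markers 0 passed over all genes and 5 adjusted over the list alone, with a median of 0.51 (camera adjusted p = 4.47e-07, adjusted p = 0.195 with an estimated correlation). Ncr1 differed by 0.75 ± 0.10, Fcer1g by 1.25 ± 0.19 and Tyrobp by 1.29 ± 0.21. The NK cell list shares Eomes and Gzma with the CD8 T cell list, and whether its rise comes from NK cells was not tested. Mast cell and basophil markers had a median of 0.39 (camera adjusted p = 5.60e-05, adjusted p = 0.241 with an estimated correlation), with 3 of 7 higher adjusted over the list alone and anti-CD3 replicate 3 apart in the list mean. Kit differed by 0.90 ± 0.13, Cpa3 by 1.00 ± 0.18 and Mcpt8 by 0.84 ± 0.20. Macrophage and monocyte markers had a median of 0.25 (camera adjusted p = 0.000333, adjusted p = 0.266 with an estimated correlation), with 1 of 11 higher adjusted over the list alone. Csf1r differed by 0.47 ± 0.097, Cd68 by 0.31 ± 0.093 and Lyz2 by 1.89 ± 0.58, with anti-CD3 replicate 4 apart for Lyz2. The macrophage and monocyte median was 0.42 without anti-ICOS replicate 1 and 0.084 without anti-ICOS replicate 2. The dendritic cell median was 0.17 without anti-ICOS replicate 1, and the mast cell and basophil median 0.24 without anti-ICOS replicate 2. With the filter on dim genes the dendritic cell median was 0.34 and the NK cell median 0.92. Against replicate 4 alone the medians were 0.12 for macrophages and monocytes, 0.22 for dendritic cells and 0.64 for mast cells and basophils.

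Neutrophil markers had a median of 0.16 (camera adjusted p = 0.0143, adjusted p = 0.370 with an estimated correlation), with 4 of 10 higher adjusted over the list alone. Mpo read 7.27 and 9.12 on the anti-ICOS arrays against a mean of 6.52 ± 0.15 (SD, n = 4) with anti-CD3, Elane 7.17 and 8.60 against 6.80 ± 0.044 (SD, n = 4). S100a8 differed by 0.45 ± 0.13. Platelet markers had a median of 0.33 (camera adjusted p = 0.00878, adjusted p = 0.356 with an estimated correlation), with 0 of 6 passing either way. Gp9 differed by 0.26 ± 0.083, Itga2b by 0.40 ± 0.14 and Pf4 by 0.52 ± 0.19. CD8 T cell markers had a median of 0.28 (camera adjusted p = 0.000996, adjusted p = 0.314 with an estimated correlation), with 2 of 8 higher adjusted over the list alone. Gzmk differed by 0.66 ± 0.14, Gzma by 0.43 ± 0.12 and Eomes by 0.59 ± 0.26. The other marker lists were not called, with 0 members passing over all genes or adjusted over the list alone. The B cell median was 0.16 (camera adjusted p = 0.347), with Fcer2a at -0.50 ± 0.16, Ms4a1 at 0.19 ± 0.13 and Blk at 0.32 ± 0.17, the latter with anti-CD3 replicate 4 apart. Stromal and endothelial markers had a median of -0.13 (camera adjusted p = 0.194), with Madcam1 at -0.33 ± 0.096, Vcam1 at 0.25 ± 0.10 and Kdr at 0.19 ± 0.091. The 3 gamma-delta T cell markers had a median of -0.097 and a mean of 0.027, with the test pointing down (camera adjusted p = 0.920). Cd163l1 differed by -0.14 ± 0.089 and Sox13 by -0.097 ± 0.11. The 4 erythroid markers had a median of 0.030 and a mean of -0.012, with the test pointing up (camera adjusted p = 0.706). Alas2 differed by 0.12 ± 0.072, Slc4a1 by -0.22 ± 0.14 and Epb42 by 0.031 ± 0.086. Without anti-CD3 replicate 4 the neutrophil and platelet lists were not called (camera adjusted p = 0.289 and 0.165), and neither was the platelet list without anti-ICOS replicate 2 (median 0.089, camera adjusted p = 0.190). The filter on dim genes ended the calls of CD8 T cell and platelet markers (medians 0.12 and 0.15, camera adjusted p = 0.0535 and 0.236), and array weights those of neutrophil and platelet markers (camera adjusted p = 0.160 and 0.0956). With an offset of 64 the neutrophil median was 0.092 and the platelet median 0.21, and against replicate 4 alone the neutrophil median was 0.32. With replicate 4 as the only reference the CD8 T cell list was not called (median -0.085, camera adjusted p = 0.930), while B cell markers were called lower (median -0.071, camera adjusted p = 0.0261) and erythroid markers higher (median 0.10, camera adjusted p = 0.0171). These 2 calls had adjusted p = 0.628 and 0.465 with an estimated correlation.

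**Figure D3:**
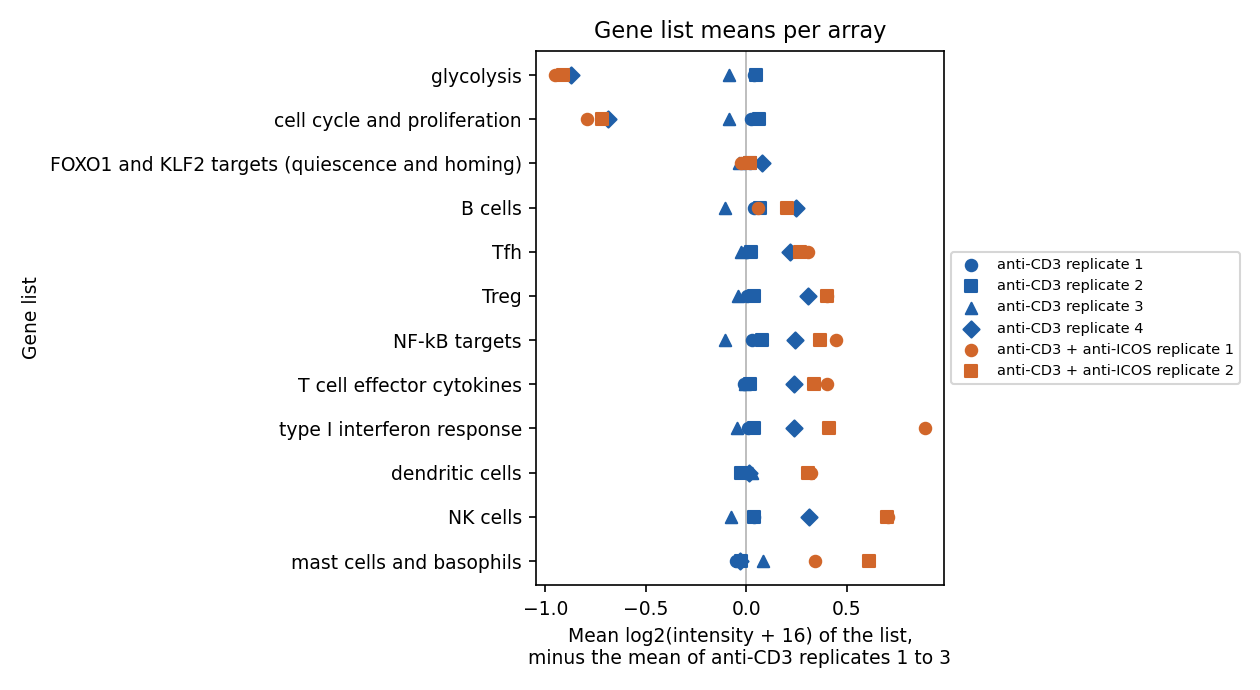
Mean log2(intensity + 16) of 12 gene lists on each array, less the mean of anti-CD3 replicates 1 to 3, with 1 point per array. Glycolysis lies at -0.87 in anti-CD3 replicate 4 and at -0.95 and -0.91 with anti-ICOS, while the dendritic cell list lies at 0.014 in replicate 4 and at 0.32 and 0.31 with anti-ICOS.

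In all, camera with a preset correlation called 25 of 33 lists, 23 higher and 2 lower, and with an estimated correlation 0, the smallest adjusted p being 0.195. Fry asks whether the genes of a list move 1 way without comparing them with other genes, and 4 lists passed. These were Th17 (adjusted p = 0.0118), dendritic cells (adjusted p = 0.00301), NK cells (adjusted p = 0.0278) and mast cells and basophils (adjusted p = 0.0335). Whether they pass by fry without anti-CD3 replicate 4, or with it as the only reference, was not tested.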

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

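The test of dendritic and myeloid genes, the test of HIF target genes and the test of a wrong label were set out before their results were seen; the tests of the rises against replicate 4, as the only reference, exchanged with an anti-ICOS array or by its place in the 143 genes, and the setting of the HIF ratio against the quartiles of all 5930 genes, were chosen afterwards. Among 165 named genes, list means and the first component, 18 had 1 of the 4 anti-CD3 arrays far from the others, measured as the gap to its nearest neighbour over the whole range. Chance gives such a gap in about 1 in 20 groups, and 8.69% of all 19937 genes had one. In 13 of the 18 the array apart was replicate 4.

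Replicate 4 was the array apart for Maf (gap over range 0.947), Lyz2 (0.963), Atp7b (0.940), Pdk1 (0.921), Klhl6 (0.909), Blk (0.881), Btg1 (0.875), Tnfrsf9 (0.874), Pdcd1 (0.851), Bcl2l1 (0.847) and Icosl (0.830). It was also apart in the means of the effector cytokine list (0.887) and the glycolysis list (0.855). Replicate 2 was apart for Ifitm3 (0.832) and Il21 (0.877), replicate 1 for Anxa3 (0.876), and replicate 3 for Cd101 (0.859) and the mast cell and basophil list mean (0.830).

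Anti-CD3 replicate 4 resembled the anti-ICOS arrays: over the 5930 genes called without it, it lay at a median of 0.999 of the way from replicates 1 to 3 to anti-ICOS. An anti-ICOS culture under a wrong label is argued against where its cell makeup matched the others, since replicate 4 fell below the halfway point in 72 of 143 genes at least 2-fold higher with anti-ICOS, while the anti-ICOS arrays left out in the same way did so in 1 of 91 and 0 of 76. A difference in culture or handling shared by replicate 4 and the anti-ICOS arrays stays open: HIF target genes lay at -0.63 in replicate 4 and -0.61 with anti-ICOS (ratio of median shifts 1.03 over 16 genes), but the middle of the 5930 genes spans ratios of 0.779 to 1.21 between quartiles, so this ratio sets no explanation apart from the others. An anti-ICOS culture with fewer myeloid cells, and a stronger response of replicate 4 to anti-CD3, also stay open and were not tested.

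The second pattern is the rise of genes with anti-ICOS. Among the 143 genes at least 2-fold higher, chosen without replicate 4, replicate 4 fell below the halfway point in 72, against the 1 of 91 and 0 of 76 above. These are the counts already used for the wrong label, so they add no separate support. With 3 arrays, 1 can also lie apart from the other 2 without an effect of ICOS. The counts argue against a difference shared with replicate 4 as the whole cause only where the cell makeup was alike. Whether it was alike is not known, so they do not exclude such a difference. For the 54 genes called, chosen with replicate 4 in the anti-CD3 group, such a difference stays open: exchanging it with anti-ICOS replicate 1 or 2 in the same limma fit gave 0 and 0 higher genes against 54, but 1578 and 1988 against 1245 at an unadjusted p under 0.05. Of the 24 calls that ended with replicate 4 as the only reference, 16 had a smaller difference and a larger SE, 3 only a smaller difference and 5 only a larger SE, with medians of 0.79 before and 0.69 after for the difference and 0.099 and 0.11 for the SE. More dendritic or other myeloid cells in the anti-ICOS cultures may contribute. Both anti-ICOS arrays lay above all 4 anti-CD3 arrays in 18 of 28 further dendritic and myeloid genes. By list it was 10 of 12 dendritic and 8 of 16 other myeloid genes. Of the 28, chance would give 1.87, and the share measured over all genes 2.38. However, 0 of the 28 passed the test over all genes. Of the 30 genes listed, 3 were in earlier lists (15 of 25 without these). About as large a share was seen in NF-kB targets (15 of 22) and interferon response genes (14 of 23). Among the fixed cell type markers it was 4 of 10 for dendritic cells and 4 of 11 for macrophages and monocytes. It was 5 of 10 for neutrophils and 4 of 7 for mast cells and basophils. For lymphoid cells it was 5 of 8 for NK cells, 2 of 8 for CD8 T cells and 0 of 9 for B cells. The test therefore cannot tell more such cells from a rise shared with other genes. Of abundant genes of such cells, Cst3 read 11.00 with anti-CD3 and 11.69 with anti-ICOS (0.70 ± 0.12). Cst3 was past the test without anti-CD3 replicate 4 but not with all 6 arrays weighted alike. In the same order H2-Aa lay at 12.57 and 12.68 and Cd74 at 12.77 and 12.71, high levels that would hide a small share. The cells had been purified as naive CD4+ T cells. However, transcripts typical of B cells and CD8 T cells (Cd79a, Cd79b and Cd8b1, below) were read on all 6 arrays. The purification is therefore not taken to exclude other cells. A response of the T cells themselves to ICOS stays open and untested.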

How the results depend on the processing

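The fit with anti-CD3 replicate 4 as the only reference was chosen after the data were seen; all other alternatives were planned. The count of 54 genes changed stayed within 1.5 times, with 0 lower, under quantile normalization, median centring, the filter on dim genes, the trended prior, the mean of probe sets, an offset of 1 and a minimum change of 1.5-fold (46 to 66 genes). It was 26 with every probe set, 28 with an offset of 64, 35 with replicate 4 as the only reference and 85 at a threshold of 0.1. Array weights called 9413 genes (4543 higher, 4870 lower). They gave anti-CD3 replicates 1 to 4 weights of 4.53, 1.07, 0.38 and 0.15, so replicate 1 dominated the weighted anti-CD3 mean. Leaving out 1 array gave 16 to 5930 changed genes, 16 to 3404 higher and 0 to 2526 lower; it was 18, 16, 20 and 5930 without anti-CD3 replicates 1, 2, 3 and 4, 36 without anti-ICOS replicate 1 and 26 without anti-ICOS replicate 2. The groups share only the replicate numbers 1 and 2, whose deviations correlated at -0.039 and 0.10. With 2 anti-ICOS arrays, the deviations of anti-ICOS replicate 1 mirror those of anti-ICOS replicate 2. These values therefore cannot show whether samples of the same number share more than a number. Replicate number as a block called 6551 genes (3389 higher, 3162 lower), a contrast that replicates 3 and 4 do not enter. The block also called 19 lists, without the inhibitory receptor, apoptosis, amino acid, heat shock, neutrophil and platelet lists (camera adjusted p = 0.0854, 0.0859, 0.260, 0.0983, 0.121 and 0.112). The 25 lists called became 16 with the filter, which left too few mast cell, neutrophil and erythroid markers for a test, 20 with array weights, 4 by fry and 0 with an estimated correlation. Some directions turned. Without anti-CD3 replicate 4 the FOXO1 and KLF2 median was 0.017 (-0.029 to 0.017 with each array left out). The median of the T cell receptor complex list turned without anti-CD3 replicate 2, anti-CD3 replicate 4 or anti-ICOS replicate 1 (-0.058 to 0.032 with each array left out) and that of oxidative phosphorylation without anti-CD3 replicate 2 (0.0042), while their tests kept their direction. With replicate 4 as the only reference the medians were 0.030 for cholesterol synthesis, 0.0019 for oxidative phosphorylation, -0.071 for B cells, -0.085 for CD8 T cells and 0.042 for stroma, and the differences were -0.079 for Bcl6, -0.037 for Cxcr5, -0.068 for Blk, -0.071 for Ms4a1, -0.020 for Eomes, 0.062 for Sox13, 0.099 for Slc4a1, -0.016 for Cd79b, -0.070 for Cd8b1 and 0.18 for Cd74. The test of gamma-delta T cell markers turned upward with array weights (median -0.065), with the block (-0.064) and without anti-CD3 replicate 4 or anti-ICOS replicate 1; with each array left out the median was -0.14 to -0.041. That of erythroid markers turned downward with array weights (0.014), without anti-CD3 replicate 4 (-0.035) and without anti-ICOS replicate 1 (-0.019), and with each array left out the median was -0.035 to 0.079. Epb42 was -0.082 without anti-ICOS replicate 1 (-0.082 to 0.14 with each array left out), and Cd74 0.013 (-0.15 to 0.013). The cause of these changes was not tested. Signal over background is not given in the sources used here, so its limit on dim genes is unknown.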

Other observations

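Transcripts typical of B cells and CD8 T cells were read on all 6 arrays of these CD4+ cultures. Cd79a, a part of the B cell receptor, lay at 12.26 ± 0.071 (SD, n = 4) with anti-CD3 and 12.18 ± 0.10 (SD, n = 2) with anti-ICOS on the log2 scale, and Cd79b at 12.48 ± 0.15 (SD, n = 4) and 12.64 ± 0.087 (SD, n = 2). Cd8b1, a chain of the CD8 receptor, lay at 11.59 ± 0.12 (SD, n = 4) and 11.69 ± 0.017 (SD, n = 2). None of these 3 genes, chosen after their values were seen, passed the test by limma (adjusted p = 0.563, 0.465 and 0.564), while with array weights Cd79b and Cd8b1 did.

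Among the genes that rose with anti-ICOS outside the fixed lists, Fabp5, a fatty acid carrier, rose by 1.18 ± 0.083 (adjusted p = 0.00330) and Hmox1, the heme-degrading enzyme, by 1.32 ± 0.11 (adjusted p = 0.00675), both chosen after their values were seen. Their adjusted p was 0.00308 and 0.0106 against replicate 4 alone. The call of Hmox1 ended without anti-CD3 replicates 2 or 3 or either anti-ICOS array (adjusted p up to 0.0890). Of 13120 probe sets with no symbol or several, 0 passed the limma test over every probe set, with 1259 at an unadjusted p under 0.05.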
